A study of Clonorchis sinensis with 7 samples.

How the data were processed

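RNA of the liver fluke Clonorchis sinensis was measured on a custom single-colour oligonucleotide array at 2 life stages. Per the labels, 4 samples were whole newly excysted juveniles (worms just freed from the metacercarial cyst) and 3 were adult worms. The group and replicate number of each sample were taken from its title. Nothing in the labels says whether the samples of a stage came from separate batches of worms or separate hosts, so the p-values measure the spread between these samples, which may be partly technical. Per the labels' protocols, RNA was amplified into biotin-labelled antisense RNA and detected with Cy5.

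The deposited file of each array gives, per the file headers, the median foreground pixel intensity of each spot on a linear scale, with no background column and a 16-bit ceiling of 65535. The scanner and image software are not given in the sources used here. All 7 files share 12396 spots with the same names and probe sequences, most probes being 35 bases long. Per the labels and the control column of the files, 779 of these spots are controls, of which 453 serve as negative controls (the files list plant, phage and bacterial oligonucleotides there, while the labels describe them as empty) and 326 as positive controls. The other 11617 spots carry 11493 different C. sinensis probes, since 31 probes were spotted 5 times. The juvenile files hold 12544 rows and the adult files 12396, so the file layout differs between the stages. No slide or scan date is given, and stage and hybridisation or scan run cannot be told apart. The adult arrays had the higher background, with negative-control medians of 390 to 436 against 83 to 137 on the juvenile arrays. The deposited series table holds log2 values by the authors for 9812 of the probes. Set against the scanner values through the probe number, each column ran linearly (correlation of at least 0.999) with log2 of the intensity minus a constant of 70 to 110 on juvenile arrays and 320 to 360 on adult arrays. The column medians lay between -0.05 and 0.03, so the values are centred per array and their direction is positive. How the constant was chosen is not given in the sources used here. This table was used as an alternative.

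Intensities were background-corrected with the normexp method (offset 50, fitted on all spots), control spots were left out, and log2 values were quantile-normalized between arrays. Spots of 1 probe were averaged. No filter on dim probes was applied. Adults were compared with juveniles with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over all 11493 probes. A probe was said to differ at an adjusted p under 0.05. All differences are adult minus juvenile on the normalized log2 scale, and an error after ± is the SD over arrays of a stage or, for a difference, its standard error. The array number, 3 against 4, limits the precision.

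A probe counted as above background on an array when its intensity exceeded the 95th percentile of the negative-control spots of that array, a rule set after the files were examined. That level was 270.4 to 424.3 on juvenile arrays and 898.6 to 1289 on adult arrays, and 48.9% to 55.3% of probes on juvenile arrays and 40.1% to 45.6% on adult arrays exceeded it. A probe above background on no array of a stage, or saturated on every array of a stage, has only a bound there. Its fold is given as "at least", computed from the mean of the brighter stage against the mean, in the dimmer stage, of the higher of the probe's own signal and the lowest normalized signal among probes above background on that array. This bound comes from means of quantile-normalized values and carries no error, so a small bound is not a guaranteed minimum. Where a probe was above background on no array of either stage, no fold is given.

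Gene names are those of the probe comment column of the array files. They are old database matches in other organisms, and 4028 of the 11493 probes have one. No genome was used, so probes are identified by contig name and not by genome position. Different probes of a gene were kept apart, and they can disagree in direction. A probe can also bind transcripts of near-identical gene copies. 31 gene lists were matched to the descriptions by text patterns written before the data were examined, as were the design, the tests and most of the other settings. Each list was tested with limma's camera against all other described probes with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. fry was run beside it. The patterns also matched 145 of 1452 list memberships by accident of wording. The lists were kept as written, and a version without these members, picked from the descriptions alone, was an alternative.

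The genes named follow a rule written before the data were examined, except that the level for being above background in it was set afterwards, as the files give no detection call. Among differing probes whose stages do not overlap, that are above background in the higher stage and that have a description other than hypothetical, unknown, uncharacterized or none, the 12 largest fitted differences in each direction were taken, which for undetected or saturated probes are not measured sizes, 1 probe per description. From each list, up to 4 members past the threshold with the largest fitted differences were taken, and from the long list of quantitative PCR reference genes the 4 of highest mean signal.

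Whether arrays of a stage could be copies of 1 hybridisation was checked on the 31 probes with 5 spots, by an F ratio of between-probe over within-probe variation in the difference of 2 arrays. 8 of the 9 pairs within a stage differed beyond the spot noise. The F ratio was largest for adult 3 against adults 1 and 2 (15.9 and 14.4) and at most 3.46 for the other pairs within a stage. Juveniles 3 and 4 did not differ beyond the spot noise (F = 1.49). That noise was large (SD 0.336) beside the SD of their difference over all probes (0.357), so the check cannot decide for this pair. They were kept as 2 samples, with their average as an alternative. The whole procedure was tested on simulated arrays with known changes. Among 11493 simulated probes, 100 were changed 2-fold and 100 were changed 4-fold, evenly in both directions and leaving out the dimmest probes. It recovered 62.0% of the 2-fold and 91.0% of the 4-fold changes, and 4.38% of its calls were unchanged probes. In the real data 65.6% of probes were called, so this share of false calls need not hold there.

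Alternatives covered the normalization between arrays, the background correction, filters on dim probes, the authors' log2 table, the variance model, averaging over probes of a gene, a replicate block, and leaving out each array. Added after the data were seen were a background correction from the negative controls, subtraction of their median, removal of a smooth surface over each array, averaging juveniles 3 and 4, a restriction to probes above background in a stage, and the lists without accidental matches. A comparison of mean with median pixel intensity was planned but not run, since only the median is in every file. Figures were drawn with matplotlib 3.10.9.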

Results

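Transcript levels of the liver fluke Clonorchis sinensis were compared between 4 samples of whole newly excysted juveniles and 3 samples of adult worms. The aim was to describe how gene expression differs between worms just freed from the cyst and mature worms. A single-colour array with 11493 different C. sinensis probes was used, of which 4028 carry a gene description. On the juvenile arrays 5625 to 6354 probes were above background, and on the adult arrays, where the background level was higher, 4603 to 5240. Correlations of normalized log2 signal across probes were 0.930 to 0.993 between juvenile arrays, 0.972 to 0.987 between adult arrays and 0.639 to 0.737 between arrays of different stages. Juvenile 2 stood apart from the other juveniles, with a median correlation of 0.964 to its own stage against 0.981 or 0.982 for the other 3.

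Among the probes with the largest fitted differences, signals of an egg protein, a tyrosinase, an axonemal dynein, antigens and enzymes of sugar metabolism were higher in adults, while those of heat shock protein 70, troponin I and a myosin light chain were higher in juveniles. In all, 7545 probes (65.6%) differed between the stages at an adjusted p under 0.05 in limma, 3784 of them higher in adults and 3761 higher in juveniles. The difference was at least 2-fold for 4509 probes, 2076 higher in adults and 2433 higher in juveniles. Of the differing probes, 4744 were above background on all arrays of the higher stage, 2242 of these higher in adults and 2502 higher in juveniles. Another 1752 differing probes were above background on no array of either stage. In adults, 455 probes were above background on all arrays and on none of the juvenile arrays, and the opposite held for 1105 probes. The background level was higher on adult arrays (898.6 to 1289 against 270.4 to 424.3), so these 2 counts do not compare the stages on equal terms. The stages did not overlap for 7528 of the 11493 probes, where chance gives 5.71% of probes. Described probes that differed were higher in adults in 38.9% of cases and undescribed ones in 56.7%. Without normalization between arrays the split was 6885 higher in adults and 1629 higher in juveniles, since the median difference of all probes then lay at 0.85 and not at 0.03. The differences are therefore relative to the bulk of the probes, and the medians of 17 of the 31 gene lists changed sign without normalization. Stage and array run cannot be told apart in these files.

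**Figure D1:**
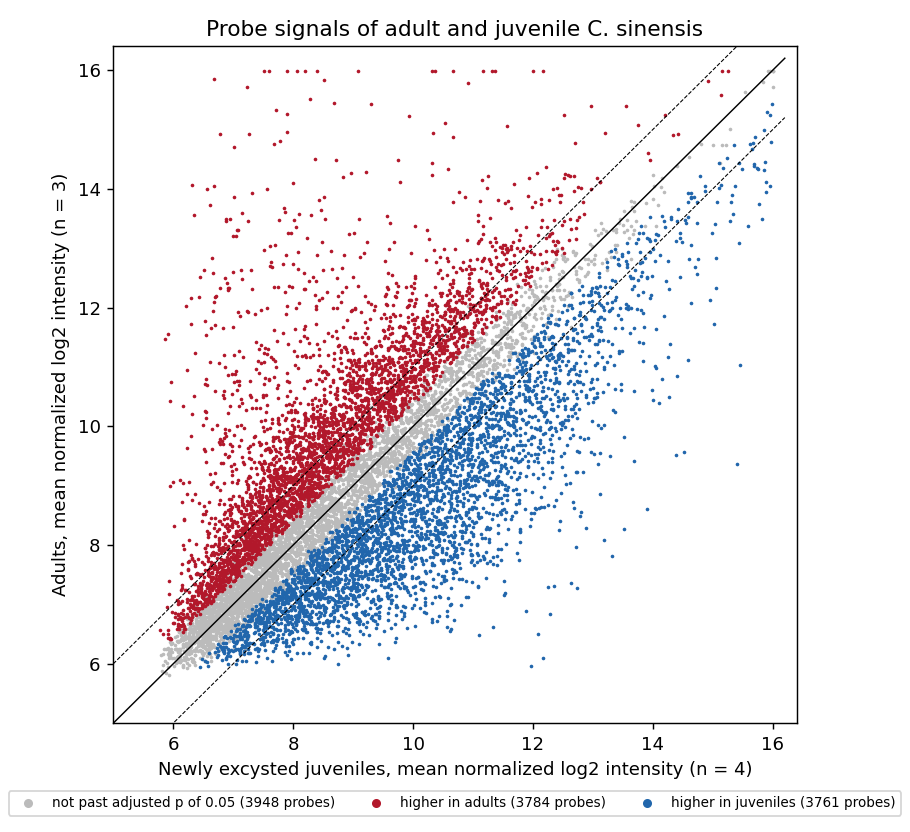
Mean normalized log2 intensity of each probe in adults (vertical axis, n = 3) against newly excysted juveniles (horizontal axis, n = 4), with 1 point per probe, a solid line of equal signal and dashed lines at a 2-fold difference. The 3784 probes higher in adults (red) lie above the line and the 3761 probes higher in juveniles (blue) below it, dim values near the background are not resolved, and the row of points at the top is saturated on the adult arrays.

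The signal of an egg protein (contig CL277Contig1) was at 15.85 ± 0.243 in adults (log2, SD, n = 3) and 6.69 ± 0.171 in juveniles (n = 4), or at least 146-fold higher in adults, as its signal was above background on no juvenile array and saturated on 2 adult arrays (limma adjusted p = 1.17e-10). A tyrosinase (CL149Contig1), an enzyme class that cross-links eggshell precursors in flukes, was at least 68.5-fold higher in adults. The probes of antigen Cs44 (CL1Contig35) and of a further antigen (CL1Contig3) were saturated on all 3 adult arrays and above background on no juvenile array, each at least 160.0-fold higher in adults. An axonemal dynein heavy chain (CSA18811), a motor protein of cilia and sperm tails, was at least 156-fold higher, with all adult arrays saturated and 2 of 4 juvenile arrays above background. The glycolytic enzymes glyceraldehyde-3-phosphate dehydrogenase (CL10Contig1) and fructose-bisphosphate aldolase (CL83Contig1) were at least 102-fold and 116-fold higher, and UDP-glucose pyrophosphorylase 2 (CL712Contig1), which makes the glucose donor of glycogen synthesis, at least 40.5-fold. A LIM domain protein similar to cysteine and glycine-rich protein 2 (CL42Contig2) was at least 78.8-fold higher. Among 3 alpha tubulin probes, CL4Contig1 had a difference of 6.76 ± 0.264 with 3 of 4 juvenile arrays above background and 1 adult array saturated, CL473Contig1 one of 7.03 ± 0.433 with only 1 juvenile array above background, and CL3765Contig1 was at least 28.4-fold higher in adults. All 12 of these probes passed an adjusted p of 2.94e-07 or smaller.

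Among probes higher in juveniles was the chaperone heat shock protein 70 (CL60Contig5), at 15.40 ± 0.277 in juveniles and 9.37 ± 0.213 in adults, a 65.1-fold difference (limma adjusted p = 2.18e-09) with 2 of 3 adult arrays above background. A heat-shock cognate 70 kDa protein (CL60Contig6) was at least 20.6-fold higher in juveniles. Some muscle probes were also higher in juveniles, with troponin I (CL1Contig41) at least 13.3-fold and a myosin light chain (CL273Contig1) 21.6-fold higher, together with the LIM proteins actinin-associated LIM protein (CL859Contig1), at least 11.6-fold, and FHL2 (CL3484Contig1), at least 11.5-fold. Complexin 1 (CL1Contig72), a regulator of synaptic vesicle release, was at least 8.73-fold higher. Its spread among juveniles was wide (12.28 ± 1.00), with juvenile 2 at 10.8 against 12.52 to 12.94 for the others. Cysteine protease 6 (CL1Contig83) was at least 12.5-fold higher in juveniles. The rest of the 12 were an unnamed protein product (CL3491Contig1), SJCHGC04891 (CSA23673), Spi12 (CSM17860), and a Sam68-like protein (CL543Contig1), at least 11.2-fold, 9.80-fold, 2.74-fold and 2.91-fold higher. The mean over all probes described as unnamed protein product had a difference of 0.09. All had an adjusted p of 7.54e-06 or smaller, although juvenile 2 lay below the other juveniles for the heat-shock cognate protein (12.33 against 13.86 to 13.94) and for cysteine protease 6 (11.42 against 13.13 to 13.41).

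**Figure D2:**
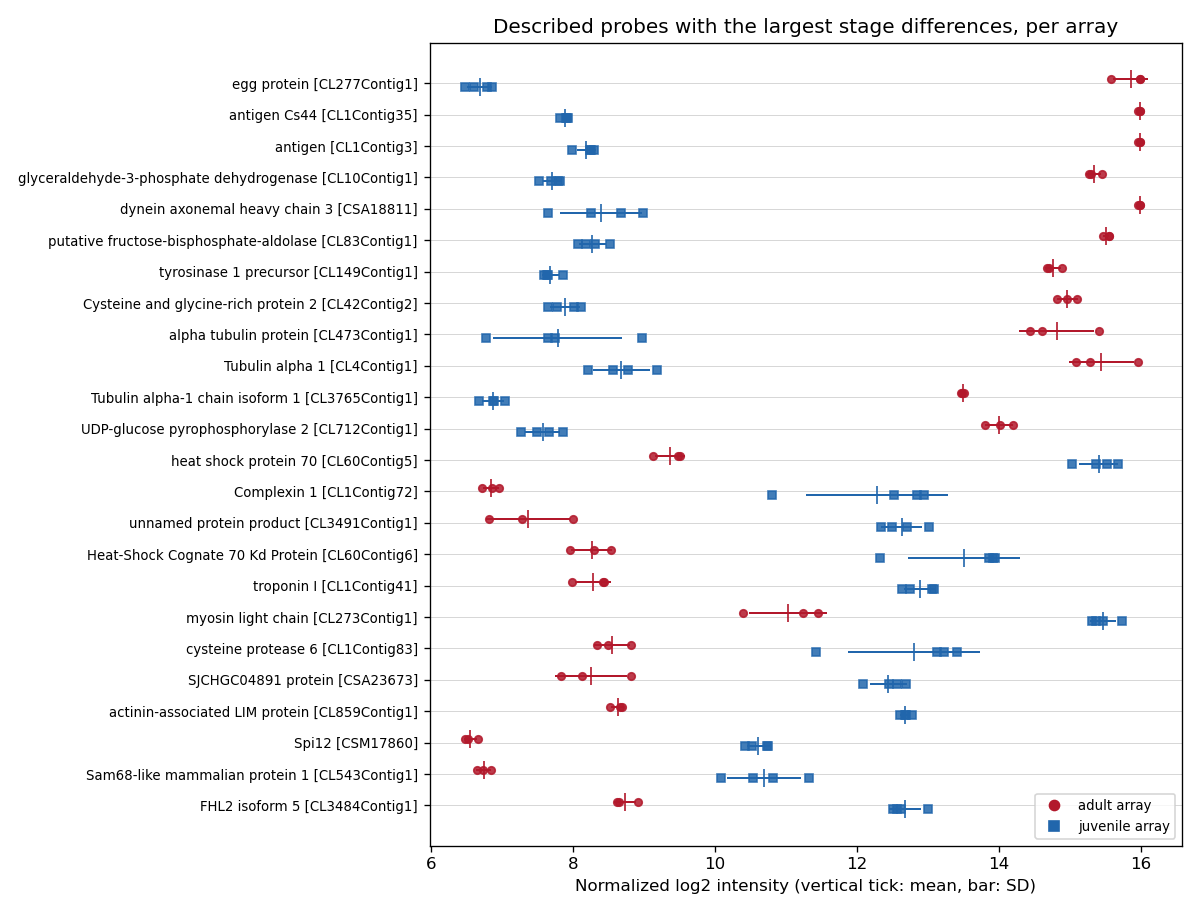
Normalized log2 intensity (horizontal axis) on each of the 3 adult arrays (circles) and 4 juvenile arrays (squares) for the 24 described probes with the largest fitted differences, with the mean as a vertical tick and the SD as a bar. No adult array overlaps a juvenile array for any of these probes, and juvenile 2 is the lowest square for heat-shock cognate 70 and cysteine protease 6.

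The lists of vitelline and eggshell, sperm and axoneme, and cysteine protease genes passed the camera test towards adults at the preset correlation. With an estimated correlation only the sperm and axoneme list did (adjusted p = 0.0126), and the adjusted p was 0.123 for each of the other two. Of 13 vitelline and eggshell probes, 9 were higher in adults and 3 higher in juveniles, with a median difference of 1.52, or 1.24 with undetected probes at their bound (camera adjusted p = 0.00209). Beside the egg protein and the tyrosinase, a vitelline B precursor (CL95Contig1) was at least 5.43-fold higher in adults, whereas a probe described as egg antigen (CL281Contig1) was at least 6.23-fold higher in juveniles. Of 74 sperm and axoneme probes, 48 were higher in adults and 6 higher in juveniles, with a median of 0.91 (adjusted p = 6.76e-09). An axonemal leucine-rich repeat protein (CL753Contig1), a radial spoke head protein (CL2500Contig1) and a second axonemal dynein heavy chain (CL2060Contig1) were at least 57.7-fold, 9.64-fold and 13.1-fold higher in adults. Of 49 cysteine protease probes, 29 were higher in adults and 11 higher in juveniles, with a median of 0.98 (adjusted p = 0.00117). A cysteine protease (CL3Contig11), cysteine proteinase 1 (CL3Contig2) and cathepsin B1 (CL1269Contig1), enzymes of the fluke gut, were at least 39.6-fold, at least 28.1-fold and 11.2-fold higher in adults, in contrast to cysteine protease 6. Adjusted over the list alone, 12, 55 and 41 members of these lists passed. Of the members higher in adults, 7, 32 and 23 were above background on all adult arrays. Of those higher in juveniles, 3, 5 and 9 were above background on all juvenile arrays. With the mean of a gene's probes the adjusted p was 0.0984 for both the vitelline list and the cysteine proteases.

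Ribosomal proteins and mitochondrial energy enzymes passed the camera test towards juveniles at the preset correlation, but not with an estimated correlation (adjusted p = 0.292 for each). Of 91 ribosomal protein probes, 67 were higher in juveniles and 6 higher in adults, with a median of -1.30 (camera adjusted p = 3.44e-05), and 74 passed when adjusted over the list alone. Ribosomal proteins S11 (CL2619Contig1) and L37 (CSA15426) were 11.8-fold and 8.34-fold higher in juveniles, and probes for L7 (CL5522Contig1) and L17 (CL230Contig1) 8.97-fold and 8.62-fold, the last with 2 of 3 adult arrays above background. Of 87 probes of the tricarboxylic acid cycle and oxidative phosphorylation, 51 were higher in juveniles and 15 higher in adults, with a median of -0.74 that lay at 0.04 without normalization between arrays (adjusted p = 0.0312, 66 passing when adjusted over the list alone). Above background on all arrays of the higher stage were 47 of the 51 and 8 of the 15, and for ribosomal proteins 63 of the 67 and 4 of the 6. The iron-sulfur subunit of succinate dehydrogenase (CL408Contig1) was 10.5-fold higher in juveniles with 2 of 3 adult arrays above background, a ubiquinol-cytochrome c reductase binding protein (CL4817Contig1) at least 3.18-fold, and 2 mitochondrial malate dehydrogenase probes (CL513Contig1 and CL46Contig1) at least 2.77-fold and 4.34-fold. The call of the energy enzymes also ended under cyclic loess (adjusted p = 0.222), with unmoderated tests (0.107) and with the mean of a gene's probes (0.0984).

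None of the other 26 lists passed the camera test, so their members are given as counts. These counts include probes that were not above background on all arrays of the higher stage. Since camera sets a list against the other described probes, its direction was towards adults although the median lay below 0 for other proteases (-0.09), tegument (-0.13), lipid handling (-0.02), solute transport (-0.19) and reference genes (-0.04). Median and mean had opposite signs for cell cycle, histones, G proteins, retrotransposons and reference genes. Of 36 glycolysis probes, 14 were higher in adults and 9 higher in juveniles (adjusted p = 0.107, 23 passing when adjusted over the list alone). Lactate dehydrogenase (CL407Contig1), a second glyceraldehyde-3-phosphate dehydrogenase (CL86Contig1) and triosephosphate isomerase (CSA14290) were at least 11.5-fold, 20.8-fold and 5.08-fold higher in adults. The list's adjusted p was 0.0373 with unmoderated tests. Glycogen and carbohydrate storage split evenly, 6 each way of 19 (adjusted p = 0.347, 12 passing over the list alone), with glycogen phosphorylase (CL1982Contig1) at least 3.68-fold higher in adults and a UDP-glucose pyrophosphorylase probe (CL3415Contig1) at least 1.39-fold higher in juveniles. The fumarate reduction and malate dismutation list had 12 of 22 probes higher in juveniles and 6 higher in adults (adjusted p = 0.747, 18 passing over the list alone). There, fumarate hydratase (CL6011Contig1) was 5.15-fold higher in juveniles and malate dehydrogenase 1B (CL567Contig1) at least 3.06-fold higher in adults. Glucose and solute transport had 44 of 101 probes higher in juveniles and 24 higher in adults (adjusted p = 0.911, 68 over the list alone). An aquaporin-1 probe (CSA06679) was 26.6-fold higher in adults and an aquaporin 9 probe (CL2257Contig1) 13.2-fold higher in juveniles. The list also holds 40 accidental matches, such as glutathione transferase.

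Muscle and contraction probes were higher in juveniles in 31 of 61 cases and higher in adults in 16 (adjusted p = 0.373, 47 over the list alone). A second troponin I probe (CL1Contig85) was at least 12.4-fold higher in juveniles, opposite to the LIM protein CL42Contig2. Neuronal, sensory and synaptic probes were higher in juveniles in 20 of 54 cases and in adults in 15 (adjusted p = 0.789, 35 over the list alone). Beside complexin 1, its named members included a shaker-related potassium channel subunit (CL2760Contig1), at least 3.35-fold, and the calcium sensor neurocalcin delta (CL3685Contig1), 6.96-fold with only 1 of 3 adult arrays above background, both higher in juveniles. Receptors and G proteins had 6 probes higher in each stage of 16 (adjusted p = 0.789, 12 over the list alone), of which 2 higher in adults and 5 higher in juveniles were above background, and the regulator of G-protein signalling 7 (CL2498Contig2) was 6.49-fold higher in juveniles. Tegument and surface membrane probes were higher in adults in 12 of 33 cases and in juveniles in 13 (adjusted p = 0.704, 27 over the list alone). Annexins, proteins that bind membranes in the presence of calcium, were among those higher in juveniles, with annexin VII (CL11Contig3) 5.62-fold, with 2 of 3 adult arrays above background, and 2 annexin B13a probes (CL287Contig1 and CL727Contig1) at least 2.81-fold and 3.51-fold. The mucin, extracellular matrix and cell adhesion list had 15 of 23 probes higher in juveniles and 4 higher in adults (adjusted p = 0.308, 21 over the list alone). Procollagen V alpha 2 (CL2898Contig1) and collagen III alpha 1 (CL1989Contig1) were at least 5.26-fold and 6.56-fold higher in juveniles, and a fibronectin type 3 and ankyrin repeat protein (CL5304Contig1) at least 11.3-fold higher in adults.

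Antioxidant and detoxification probes were higher in juveniles in 25 of 51 cases and in adults in 15 (adjusted p = 0.789, 40 over the list alone). A glutathione transferase (CL333Contig1) was at least 12.7-fold higher in adults, and thioredoxin glutathione reductase (CL587Contig1), the central thiol reductase of flatworms, at least 4.42-fold higher in juveniles. Lipid and bile acid handling had 16 of 44 probes higher in juveniles and 14 higher in adults (adjusted p = 0.789, 30 over the list alone), with a very low density lipoprotein binding protein (CL5177Contig1) at least 2.78-fold and a sodium-bile acid cotransporter (CL420Contig1) at least 1.14-fold higher in juveniles. Globins and iron handling had 9 of 16 probes higher in juveniles and 3 higher in adults (adjusted p = 0.373, 12 over the list alone), but 8 of the 16 were accidental matches, such as pyruvate dehydrogenase, and the 8 left had 2 higher in each stage. Myoglobin (CL3Contig1), an oxygen-binding protein, was saturated on all adult arrays and at least 14.1-fold higher there. Other proteases (9 of 25 higher in juveniles, 7 in adults, adjusted p = 0.789, 16 over the list alone) included an aspartic protease (CSA08845) at least 4.97-fold higher in juveniles. Protease inhibitors (2 of 6 higher in juveniles, 1 in adults, adjusted p = 0.789, 3 over the list alone) included serine protease inhibitor B3 (CL2473Contig1), at least 4.92-fold higher in juveniles.

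Heat shock proteins and chaperones were higher in juveniles in 41 of 87 cases and in adults in 12 (adjusted p = 0.373, 51 over the list alone). Another probe of the 70 kDa class (CL60Contig4) was 8.59-fold higher in juveniles, and another heat shock protein (CL2366Contig1) at least 10.1-fold higher in adults. Mitochondrial ribosomal proteins had 17 of 27 probes higher in juveniles and 3 higher in adults (adjusted p = 0.173, 20 over the list alone). Translation initiation and elongation had 47 of 96 higher in juveniles and 13 in adults (adjusted p = 0.173, 59 over the list alone), with elongation factor 1 beta 2 (CL1817Contig1) at least 5.41-fold and initiation factor 5 (CL396Contig1) 7.20-fold higher in juveniles. Ubiquitin and proteasome probes were higher in juveniles in 52 of 111 cases and in adults in 21 (adjusted p = 0.373, 73 over the list alone), with a 26S proteasome ATPase (CSM14480) 6.65-fold higher in juveniles. Vesicle traffic and secretion had 28 of 69 higher in juveniles and 13 in adults (adjusted p = 0.737, 39 over the list alone), with a sorting nexin (CL1376Contig1) at least 7.47-fold higher in juveniles.

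The oocyte, germ line and meiosis list had only 5 probes, 3 of them higher in adults and 0 higher in juveniles (adjusted p = 0.107, 3 over the list alone), and 1 pumilio 1 probe (CSM00806) was 2.05-fold higher in adults. Without adult replicate 3 the list's adjusted p was 0.0279. Cell cycle and DNA replication had 15 of 42 probes higher in adults and 11 higher in juveniles (adjusted p = 0.384, 26 over the list alone), and its named members included an accidental match to a tetracycline transporter. DNA polymerase delta interacting protein 2 (CL869Contig1) was at least 3.39-fold higher in juveniles. Histones and chromatin split evenly, 5 each way of 21 (adjusted p = 0.485, 9 over the list alone), with histone H2A family member X (CSM12175) at least 3.77-fold higher in juveniles and histone deacetylase 5 (CL4010Contig1) 2.59-fold higher in adults. Developmental signalling and transcription factors had 31 of 71 probes higher in juveniles and 16 in adults (adjusted p = 0.704, 47 over the list alone). A MYND-type zinc finger protein (CL2102Contig1) was 10.4-fold higher in adults and the homeobox protein extradenticle (CL852Contig1) 5.27-fold higher in juveniles. Retrotransposon probes were higher in juveniles in 17 of 51 cases and in adults in 16 (adjusted p = 0.704, 33 over the list alone). The 4 named members were gag-pol probes higher in juveniles, CSM00830, CL429Contig2 and CL930Contig1 at least 3.13-fold, 3.84-fold and 4.20-fold and CL429Contig1 5.46-fold.

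Of 43 probes of genes used as references in quantitative PCR, 16 were higher in adults, 18 higher in juveniles and 9 not past the threshold (adjusted p = 0.704, 34 over the list alone). Of the 4 brightest, both actin probes were higher in juveniles, with differences of -1.91 ± 0.169 (CL1Contig37, saturated on 3 juvenile arrays) and -1.32 ± 0.25 (CL1Contig53, adjusted p = 0.108 under cyclic loess). The mean over all probes described as actin had a difference of 0.18. A beta-tubulin probe (CSA08266) had a difference of 0.24 ± 0.151 (limma adjusted p = 0.191, but 0.00129 under cyclic loess and 0.00635 without normalization), and a phosphoglycerate kinase probe (CL2172Contig1) one of -0.43 ± 0.141 (adjusted p = 0.0207), whose sign turned under cyclic loess (0.15) and without normalization (0.21). Its call was lost without juvenile replicate 1 (adjusted p = 0.0704) and without adult replicate 1 (0.0645). The list of candidate host or foreign RNA had 8 probes, of which 3 were higher in adults and 2 higher in juveniles (adjusted p = 0.704, 4 over the list alone), but 7 were accidental matches. One of these, LanC-like 3 (CSM17937), had a difference of 1.22 ± 0.49 (adjusted p = 0.0482) that fell to 0.73 and lost its call without juvenile replicate 2 (adjusted p = 0.0534), and it lost its call without every other array except juvenile replicate 3 as well. The only true member, a probe matching rabbit serum albumin (CSA28013, chosen after its value was seen), was above background on no array.

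**Figure D3:**
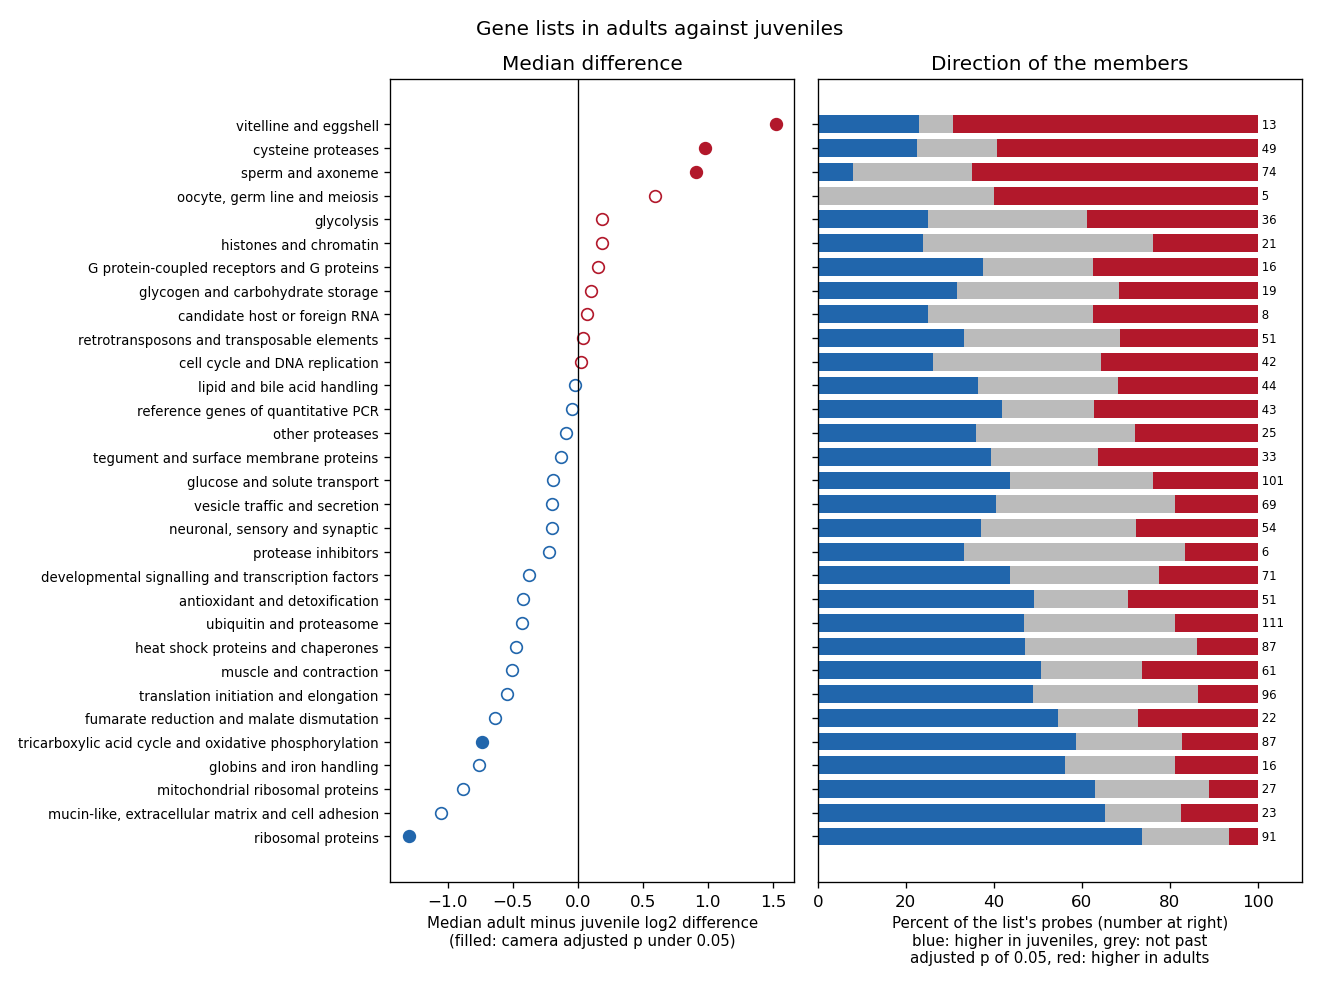
Left, median adult minus juvenile log2 difference of the probes of each of 31 gene lists, red above 0, blue below 0 and filled where the camera adjusted p is under 0.05. Right, the percent of each list's probes higher in juveniles (blue), not past the threshold (grey) and higher in adults (red), with the number of probes. The 3 lists filled above 0 have medians of 0.91 to 1.52 and ribosomal proteins the lowest at -1.30, and of the filled lists only sperm and axoneme passes with an estimated correlation.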

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

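The tests of mixture with adult material and of array runs and the spread over arrays of the ribosomal comparison were chosen only after the result was seen, and the other tests before. In the 4 juvenile samples, 136 values (8 array measures and 128 named probes) were searched for a sample far from the others, of which chance gives about 6.8. In 10 of them a sample lay beyond the critical value of the gap to its nearest neighbour over the whole range, and in 9 of these it was juvenile 2. The adult samples were not searched in this way, although the largest F ratios within a stage were those of adult 3 (15.9 and 14.4).

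The median correlation of juvenile 2 with its own stage was 0.964 against 0.981 to 0.982 for the others (gap ratio 0.944). Juvenile 2 was also lowest for heat-shock cognate 70 (12.33 against 13.86 to 13.94, ratio 0.95), cysteine protease 6 (11.42 against 13.13 to 13.41, ratio 0.860), annexin B13a of CL727Contig1 (10.29 against 11.14 to 11.22, ratio 0.916), the shaker-related channel subunit (10.21 against 11.02 to 11.19, ratio 0.831), myoglobin (11.33 against 12.43 to 12.46, ratio 0.972) and the actin probe CL1Contig53 (14.63 against 15.54 to 15.68, ratio 0.865). For the actin probe CL1Contig37 the ratio was 1.00 because the other 3 juveniles were saturated at the same value. It was highest for the ADP-ribosylation factor-like protein 6 (8.23 against 7.65 to 7.72, ratio 0.886). Juvenile 1 was highest for a serine proteinase inhibitor (CL801Contig1, 7.53 against 7.26 to 7.29, ratio 0.905), a probe above background on no array.

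Position on the array explained 39.3% of the deviation of juvenile 2 from its stage mean, against 9.59% to 47.0% on the other arrays, and its spots of 1 probe varied with the array row in the opposite sense (0.34 log2 from top to bottom) to the other 6 arrays (-0.68 to -0.11). With a smooth surface removed from each array, its median correlation with the other juveniles was 0.973, still below the lowest of the others at 0.987, which argues against position as the whole cause. Its deviation from the other juveniles correlated across probes with the adult minus juvenile difference at -0.160, the opposite sign to a mixture with adult material. What else set this sample apart stays open, and no biological explanation was tested.

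Of the 35 ways to split the 7 arrays into 4 and 3, only the real split itself gave as many differing probes (7545). In the highest of the others limma called 0 probes. The other splits put arrays of both stages in the same group, which widens their spread, so 0 calls there say little about chance. With 35 splits, 1 in 35 is also the lowest share this test can reach. At an unadjusted p under 0.05 the real split gave 7887 probes and the highest of the others 5576.

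A higher background of the adult arrays is a candidate explanation for differing probes above background on no array. Of 61 negative-control probes normalized and fitted together with the C. sinensis probes, 27, or 44.3%, were called, all higher in adults, against 44.8% of the 3834 C. sinensis probes above background on no array. Those C. sinensis calls went both ways, 1112 higher in adults and 604 higher in juveniles, and 12.5% of these probes against 6.56% of the controls were called with at least a 2-fold difference. Of the 4744 differing probes above background in the higher stage, 98.1% kept call and direction both without background correction and with a correction from the negative controls. This comparison cannot decide on background, since each correction keeps the order of spots within an array and quantile normalization follows it. Whether background has a part in these 4744 differences stays open. For these probes a difference between array runs also cannot be told apart from the stage, since 0 file layouts held arrays of both stages.

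For ribosomal proteins, lower in adults, the median difference minus that of all described probes was -1.28 without normalization or with scalings that shift all probes of an array alike, -1.07 with quantile normalization and -0.665 with cyclic loess. Leaving out adult 3 it was -0.43 with cyclic loess, above the bound of -0.5 set in advance, so the tables do not decide whether the normalization between arrays is part of the cause. The list's median of -1.30 lay at percentile 0 of 10000 random lists of described probes matched on mean signal, whose lowest median was -0.89, which argues against probe brightness. The normalization, a difference of stage, as the design names it, and a difference of array run all stay open.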

How the results depend on the processing

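The alternatives chosen after seeing the data were 6 (background from the negative controls, their median subtracted, the smooth surface, juveniles 3 and 4 averaged, the restriction to probes above background in a stage, and the lists without accidental matches), and the others were planned. The number of differing probes stayed within 1.5 times the reported 7545 in all but 1 of 27 settings, from 5199 to 8960. With only the 6050 probes above background on all arrays of a stage it was 4820 (2277 higher in adults), as fewer probes were tested. Among the 6670 probes above background on at least 3 arrays, 2340 were higher in adults. Without normalization 6885 were higher in adults and 1629 in juveniles, as each array then kept its own overall level. Only 5413 of the 7545 reported calls (71.7%) kept call and direction there, so a similar count does not mean the same probes. Leaving out 1 array gave 6759 to 7829 differing probes. Between 88.7% and 97.8% of the reported calls were then still called with the same direction. Nothing in the labels says that the replicate numbers pair the samples. Deviations of same-numbered samples correlated at -0.074, 0.25 and -0.06, and only replicate 2 deviated most like its own number in both stages. Position on the array explained part of these deviations, so the correlations cannot decide whether the numbers pair the samples. The replicate block gave 7006 differing probes, and the call of phosphoglycerate kinase was lost with it (adjusted p = 0.0663).

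The 5 gene lists called became 1 with an estimated correlation, 2 with the mean of a gene's probes, and 27 with fry, which tests a list against no change and not against other genes. The same 5 were called without accidental matches. With fry, 6 lists turned against their camera direction, 5 of them past the fry threshold at adjusted p of 0.0081 for other proteases, 0.00154 for G proteins, 0.00172 for lipid handling, 0.00468 for solute transport and 0.00168 for retrotransposons, and tegument proteins not (0.436). Without normalization the medians of 17 lists changed sign, and under another normalization those of 6.

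The gap between the lowest correlation within a stage and the highest between stages, reported as 0.193, was 0.168 with cyclic loess, 0.347 without the dimmest 30% of probes, 0.420 for probes above background on at least 3 arrays, 0.487 for those above background in a stage, 0.225 in the authors' table, 0.220 with the smooth surface removed, 0.228 with juveniles 3 and 4 averaged, and 0.193 to 0.253 leaving out 1 array. Of 128 named probes, 115 kept call and direction under every setting in which they were tested. Most of these probes were named for their large differences in the same data, so this share does not carry over to all differing probes. The sign turned for phosphoglycerate kinase without normalization (0.21) and with cyclic loess (0.15), for CSM11749 without normalization (0.089), and with the mean of a gene's probes for both actin probes (0.18) and for the unnamed protein product (0.089), which averages all probes that share a description. For the other changes the cause was not tested. Mean in place of median pixel intensity was not run. Signal over background limits the rest, as 3834 probes were above background on no array.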

Other observations

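The families in the first 2 paragraphs were chosen after the values were seen, and the test of the probe names was fixed before. Of 38 probes of alpha tubulin, a subunit of microtubules, 29 were higher in adults and 3 higher in juveniles, with a median difference of 1.54 (1.53 to 2.47 over the other scalings). Of the 29, 17 were above background on all adult arrays and 9 on no array of either stage. CL840Contig1 was at least 15.9-fold higher in adults and CL5272Contig1 had a difference of 4.30. Of 15 beta tubulin probes, 6 were higher in adults and 5 higher in juveniles, of which 5 and 5 were above background on all arrays of the higher stage. CL6Contig2, saturated on 2 of 3 adult arrays, had a difference of 4.88 and CL169Contig1 was at least 14.1-fold higher in adults, while CL3467Contig1 had a difference of -3.70 and CL813Contig1 one of -2.38, and these signs held without normalization between arrays (5.37, 6.11, -2.95 and -1.52).

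Of 25 probes of RNA splicing proteins, 19 were higher in juveniles and 3 higher in adults, with a median of -1.16 (-1.22 to -0.27 over the other scalings), and 15 and 2 of them were above background on all arrays of the higher stage. Small nuclear ribonucleoproteins D2 (CSM01243), F (CL2599Contig1) and B (CL2741Contig1) were at least 7.26-fold, 3.31-fold and 3.30-fold higher in juveniles. Of 29 calcium-binding protein probes, 16 were higher in juveniles and 5 higher in adults, with a median of -0.62 that turned positive in at least 1 other scaling (up to 0.17), and 14 and 4 were above background on all arrays of the higher stage. Among them a calponin homolog (CL310Contig1) had a difference of -3.47 and a calcium binding protein (CL917Contig1) one of -3.38. Of 20 probes of the translocon and glycosylation machinery, 11 were higher in juveniles and 2 higher in adults, of which 9 and 0 were above background on all arrays of the higher stage.

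Of 234 descriptions shared by at least 2 differing probes, 92 (39.3%) held probes differing in opposite directions.

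Names of probes from single sequences start with CSA or CSM, and a hypothesis was that the prefix may mark the stage of the library the sequence came from. Of 1920 differing CSA probes 57.9% were higher in adults, and of 1081 differing CSM probes 57.9% as well, a difference of -0.0448 percentage points (Fisher's exact test, two-sided, p = 1), so no difference between these prefixes was detected. The share was 45.0% among the 4544 differing probes named for contigs.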
